A study of Homo sapiens with 6 samples.

How the data were processed

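The data are 6 one-colour Affymetrix arrays of human total RNA, 3 labelled CL1-0 and 3 labelled CL1-5. Groups and repeat numbers were taken from the sample titles, which call the samples biological repeats. The deposited values are probe set intensity values on a linear scale, normalized between arrays by the authors. MAS5 is the 1 tool named, per the submitters' processing notes, and its version and any later step are not given in the sources used here. All values are above 0, the lowest on each array lies between 3.58 and 3.91, and the means after trimming 2% at each end lie between 151 and 159 without being equal. Whether the values are plain MAS5 output therefore stays unknown, and no detection call was used here. No scan dates were used here.

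Probe sets were named through the platform annotation. Of 54675 probe sets, 41091 had 1 gene symbol, 1801 several, 11721 none and 62 were controls, and 41037 were matched by gene identifier to the RefSeq annotation of assembly GRCh38.p14, which was used for current symbols and for the order of genes along chromosomes. No genome build is given with the values, so no coordinates are printed. Probe sets with no symbol or several were left out of the gene comparison, and XIST and Y-linked genes were counted but are not named.

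Values were turned into log2(signal + 6.85), the constant being the 10th percentile of all values. A probe set was kept where it exceeded the 40th percentile of its array on at least 3 of the 6 arrays, and each gene was represented by the probe set with the highest mean, without the cross-hybridising kind (suffix x) where another passed. This left 14828 of 19775 named genes. Among the called genes, 174 had another probe set called in the opposite direction, and no named gene was among them. The lines were compared in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a trend in the prior variance), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. P-values measure the spread between the 3 repeats of each line. Where all 3 arrays of a line lay at or under the 40th percentile, the fold is given as a bound, the bright line's mean against, per array, the higher of that percentile and the measured value. The same bound was given, after the signals were seen, to genes where the mean of a line's arrays lay there. The percentile stands in for background.

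A set of 37 gene lists was fixed, of which the 35 with at least 5 tested members went into camera with a correlation of 0.01 between genes, adjusted over the lists. Named genes were the 12 largest increases and 12 largest decreases whose lines do not overlap, up to 4 called members with the largest change in each list, every member of the list of earlier CL1 reports, and CDH1, VIM, CDH2, EPCAM and NKX2-1. Not every gene the rule takes is printed. The result of 1 list is not reported here. The groups, the tests, the lists, this rule and most of the alternatives below were fixed before the data were examined. The steps were tested on simulated data made for the comparison of CL1-5 with CL1-0, with 200 of 14828 genes changed. Recovery was 30% at a log2 change of 0.5, 90% at 1, 94% at 2 and 100% at 4, with 8 false calls (4.85% of calls), and the list test called the raised list and 0 of 34 random lists. The simulated noise was independent between genes and held no batch, and far fewer genes changed than were called in the data. The random lists therefore cannot show whether the list test calls lists of correlated genes too often.

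The labels do not say that repeat numbers mark a shared day. Deviations from the line means correlated between same-numbered arrays at 0.475, 0.280 and 0.649 over genes for repeats 1, 2 and 3. Deviations of 3 arrays sum to 0, so these values depend on one another. The numbers were taken to pair the arrays only in the paired test of RNA quality and in the alternative with the repeat number as a block. The main fit had no block, so its counts, standard errors and p-values are unpaired. Alternatives were the added constant, the filter, between-array scaling, the prior variance trend, array weights, the choice of probe set, the repeat number as a block, leaving out each array, a stricter threshold and other list tests. Added after the data were seen were the paired test of RNA quality, fits of repeats 1 and 2 alone, of the spike-in batch as a block, and leave-one-out fits with the filter on 2 arrays. The last were added because, with 3 arrays still required, a gene expressed in a line down to 2 arrays fails the filter.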

Results

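Transcript levels were measured in a pair of lung adenocarcinoma cell lines, CL1-0 and CL1-5, both derived from the parental line CL1. CL1-0 is the poorly invasive line and CL1-5 the highly invasive one. Total RNA from 3 biological repeats of each line was hybridised to 6 one-colour oligonucleotide arrays with probe sets for 19775 named genes. After filtering, 14828 genes were compared, each through 1 probe set. Array medians lay between 30.2 and 30.9 signal units, and the number of arrays limits the precision of every value below. The median standard error of a log2 fold change was 0.11. Values are log2 fold changes of CL1-5 over CL1-0 on the log2(signal + constant) scale, which understates the change of dim genes, with n = 3 arrays per line throughout.

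The 6 arrays separated by line. Pearson correlations across genes were 0.989 to 0.996 within a line and 0.856 to 0.866 between lines, and genes are not independent replicates in such a correlation. The first principal component held 93.0% of the variance and parted the lines, while the second held 4.42% and set repeat 3 of both lines apart from repeats 1 and 2. The 3′ to 5′ ratio of the control probe sets, a sign of RNA quality, averaged 0.71 ± 0.40 (log2, SD, n = 3) in CL1-0 and 0.54 ± 0.32 in CL1-5 for ACTB, with an exact two-sided permutation p of 0.5. For GAPDH it was 0.16 ± 0.09 and 0.08 ± 0.10, with an exact permutation p of 0.4. The smallest p that 3 against 3 arrays can give is 0.1. Paired by repeat number, a test chosen after the ratios were seen, both ratios were lower in CL1-5 in 3 of 3 pairs, by log2 differences of -0.17 ± 0.12 (SD) for ACTB and -0.07 ± 0.05 for GAPDH. The exact sign-flip p was 0.25 for each, the smallest that 3 pairs can give, so a difference in RNA quality between the lines is not excluded.

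**Figure D1:**
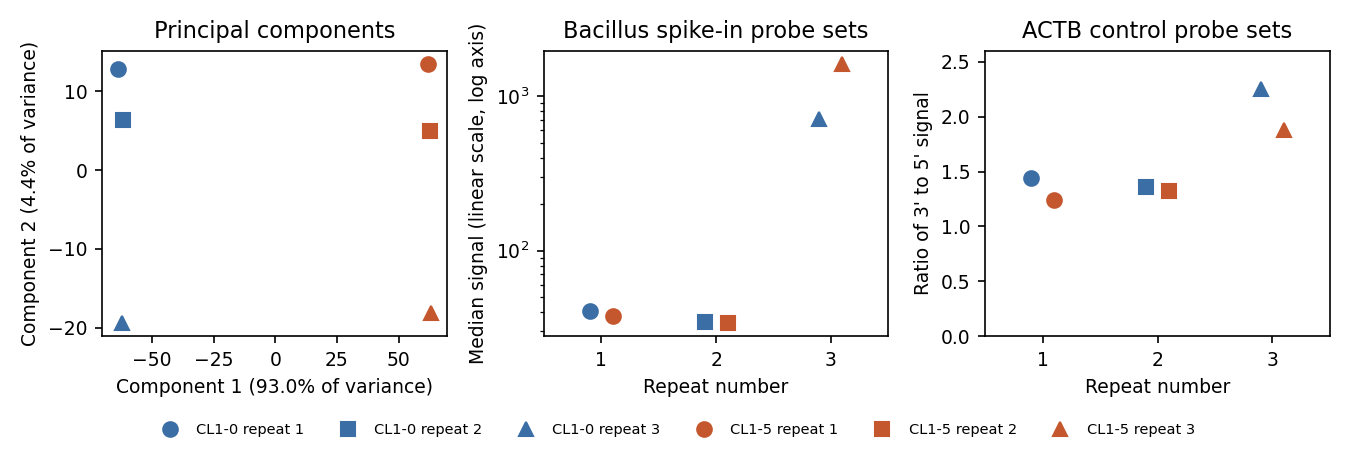
Each point is 1 array, coloured by line and shaped by repeat number. The left panel shows the first and second principal components of the log2 values, the middle panel the median signal of the Bacillus spike-in control probe sets on a log axis, and the right panel the ratio of 3′ to 5′ signal of the ACTB control. The lines part on the first component, and the repeat 3 arrays, with ratios of 2.25 and 1.88, lie above the others in the middle and right panels.

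The comparison of CL1-5 with CL1-0 asks which transcripts differ between a highly and a poorly invasive line of one origin. Among the genes higher in CL1-5 were those for the secreted glycoprotein PAEP (at least 273-fold), the calcium-binding protein S100A6 (at least 202-fold), the urokinase plasminogen activator PLAU (from 21.4 ± 3.49 to 7206 ± 182 signal units, SD), the chemokine CXCL8 (at least 189-fold) and the interferon-induced GTPase MX1 (at least 190-fold). Among the genes lower in CL1-5 were those for the gap junction protein connexin 43, GJA1 (at least 274-fold), the aldehyde dehydrogenase ALDH1A1 (at least 183-fold), the transcription factor SOX2 (at least 155-fold), the microtubule-associated protein MAP2 (at least 137-fold) and osteopontin, SPP1 (log2 fold change -7.27, SE 0.15). In all, 3448 genes were higher and 4196 lower in CL1-5 by limma's moderated test with Benjamini-Hochberg adjustment at an adjusted p under 0.05, together 51.6% of the genes tested. Of these, 1262 were at least 2-fold higher and 1127 at least 2-fold lower, and 276 and 102 passed 8-fold. For 8723 genes, 58.8% of those tested, all arrays of one line lay above all arrays of the other, against 10% by chance.

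For several of these genes one line lay, on every array or on average, at or under the 40th percentile of its arrays, taken here as a stand-in for background, so that the fold is a lower bound and such genes have no order among themselves. GJA1 averaged 7317 ± 231 signal units (SD) in CL1-0 and 6.36 ± 0.51 in CL1-5. CXCL8 averaged 14.6 ± 4.45 in CL1-0 and 5174 ± 1253 in CL1-5. THBD, the endothelial anticoagulant receptor thrombomodulin, was at least 101-fold higher, the hyaluronan-binding protein CEMIP at least 107-fold, the ubiquitin ligase DTX3L at least 116-fold and the Notch-related membrane protein DNER at least 83.0-fold. The other genes among the 12 with the largest computed increase were SNAI2, IFI27 and OAS1, described below with their groups. The other genes among the 12 with the largest computed decrease were the nuclear receptor NR2F1 (at least 80.3-fold lower), the matrix protein SPARCL1 (at least 64.4-fold), stem cell factor KITLG (at least 74.9-fold), the thrombin receptor family member F2RL2 (at least 43.5-fold), periostin POSTN (at least 41.2-fold), the kinase TAOK1 (at least 37.5-fold) and the protease inhibitor TFPI2 (at least 44.3-fold). When CL1-0 repeat 1, 2 or 3 was left out, the bright TAOK1 probe set failed the filter on 3 arrays and another was tested, with log2 fold changes of -0.16, -0.09 and -0.18 and adjusted p of 0.27, 0.55 and 0.22.

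**Figure D2:**
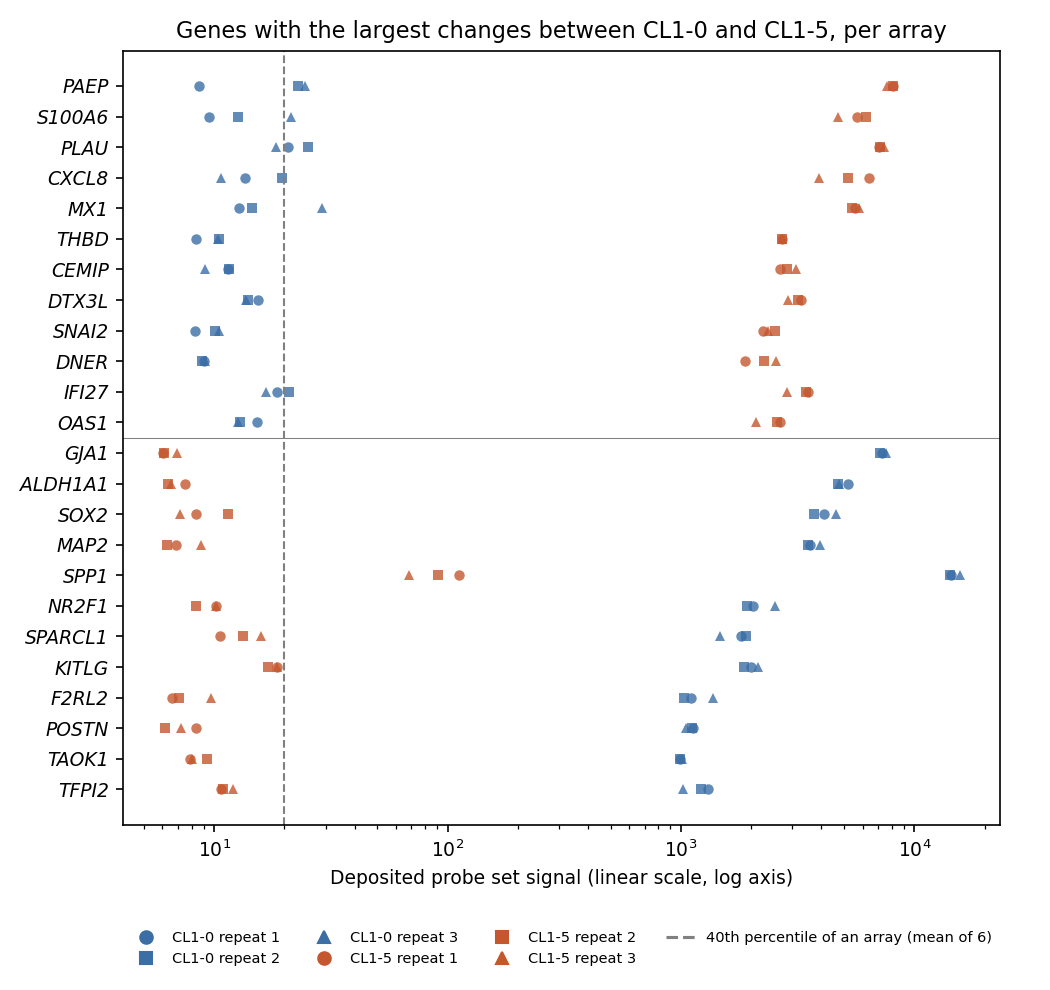
Signal on a log axis of the 12 genes with the largest increase (upper part) and the 12 with the largest decrease (lower part) in CL1-5, with 1 point per array, coloured by line and shaped by repeat number. The dashed line marks the mean 40th percentile of the arrays. GJA1 falls from 7317 in CL1-0 to 6.36 in CL1-5, and for every gene shown the arrays of the lines do not overlap.

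Interferon-stimulated genes were higher in CL1-5 without exception. All 37 tested members of the interferon response list rose, also when adjusted over the list alone, with a median log2 fold change of 4.35 and a smallest of 1.39. Among them were MX1, IFI27 (at least 120-fold), the 2′-5′-oligoadenylate synthetase OAS1 (at least 91.2-fold) and the membrane protein IFITM1 (6.73, SE 0.12). The list passed camera, limma's competitive test with a preset correlation between genes, at an adjusted p of 3.3e-28, and held with an estimated correlation at an adjusted p of 0.025. Its median was 4.42 within repeats 1 and 2 and 4.36 within repeat 3.

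Genes of MHC class I antigen presentation rose with them. Of 17 tested members 16 were higher and 0 lower, and 17 were higher when adjusted over the list alone, with a median of 2.10. The immunoproteasome subunits PSMB8 (at least 68.6-fold higher) and PSMB9 (4.99, SE 0.12), the peptide transporter TAP1 (3.85, SE 0.08) and the class I transactivator NLRC5 (3.40, SE 0.15) were among the genes that rose. The list had a camera adjusted p of 6.4e-11 and one of 0.025 with an estimated correlation. Its median was 2.07 within repeats 1 and 2 and 2.24 within repeat 3. The class II list did not pass (camera adjusted p = 0.63), with 2 of 9 members higher and 2 lower, among them the protease CTSS (at least 14.7-fold), HLA-DQB1 (1.23, SE 0.11), HLA-DRB1 (-0.81, SE 0.10) and HLA-DMA (-0.58, SE 0.13). HLA genes share sequence with near-identical relatives, so the values of single ones are uncertain. The HLA-DQB1 call was lost with no filter.

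Inflammatory cytokines and chemokines were higher in CL1-5 in 19 of 23 tested genes and lower in 1, the same counts as when adjusted over the list alone. CXCL8, the chemokine CXCL1 (6.63, SE 0.21), interleukin 6, IL6 (6.54, SE 0.15), and interleukin 1 alpha, IL1A (at least 35.9-fold), were among the genes that rose. The median log2 fold change was 2.40, or 2.13 with the dim genes at their bound, and the list had a camera adjusted p of 1.8e-10, which became 0.025 with an estimated correlation. Its median was 2.31 within repeats 1 and 2 and 2.43 within repeat 3. When CL1-5 repeat 1, 2 or 3 was left out, IL1A was tested through another probe set that passed the filter on 3 arrays, with values of -0.30, -0.32 and -0.54 and adjusted p of 0.44, 0.45 and 0.13.

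Proteases of the extracellular matrix and their inhibitors rose in 18 of 25 tested genes and fell in 4, also when adjusted over the list alone, with a median of 1.63. PLAU, its receptor PLAUR (5.57, SE 0.14), the interstitial collagenase MMP1 (4.42, SE 0.11) and the cathepsin CTSS were among the genes that rose. The camera adjusted p was 3.5e-06, and 0.035 with an estimated correlation. The median was 1.65 within repeats 1 and 2 and 1.60 within repeat 3.

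Mesenchymal markers rose in 13 of 19 tested genes and fell in 2, also when adjusted over the list alone, with a median of 1.49. The hyaluronan receptor CD44 was at least 45.0-fold higher, and the lysyl oxidase LOXL2 (5.69, SE 0.13) and the ecto-5′-nucleotidase NT5E (5.37, SE 0.13) rose, whereas POSTN fell. The intermediate filament gene VIM was bright in both lines, at 11975 ± 661 signal units (SD) in CL1-0 and 13773 ± 1094 in CL1-5, with a log2 fold change of 0.20 and an adjusted p of 0.046. The VIM call was lost without CL1-0 repeat 1 (adjusted p = 0.16) or 2 (0.095) and without CL1-5 repeat 2 (0.10) or 3 (0.14). It was also lost with no filter (adjusted p = 0.070), with no trend in the prior variance (0.11) and over all probe sets (0.055). CDH2, N-cadherin, was dim in both lines and differed by 0.09 (adjusted p = 0.49). The list had a camera adjusted p of 2.8e-05, and of 0.045 with an estimated correlation. Its median was 1.49 within repeats 1 and 2 and 1.47 within repeat 3.

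All 11 tested transcription factors of epithelial to mesenchymal transition differed between the lines, 7 higher and 4 lower in CL1-5, also when adjusted over the list alone. SNAI2 was at least 88.8-fold and SOX9 at least 62.4-fold higher, TCF4 rose by 2.67 (SE 0.15), and TWIST1 was at least 16.1-fold lower. The list as a whole did not pass (camera adjusted p = 0.18), though it did without CL1-0 repeat 2 (adjusted p = 0.042) or 3 (0.047). With the filter on 2 arrays, which keeps genes expressed in CL1-0 alone, it passed in no fit without 1 array.

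Epithelial genes showed no common direction. Of 22 tested junction genes 6 were higher and 9 lower, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.74). The desmosomal plaque protein DSP rose by 2.53 (SE 0.07) and CLDN1 by 1.39 (SE 0.13), while the protease inhibitor SPINT2 (-2.31, SE 0.11) and the desmosomal cadherin DSC2 (-1.94, SE 0.09) fell. The epithelial adhesion molecule EPCAM was at least 1.35-fold lower, at low signals in both lines. CDH1, E-cadherin, was dim in both lines, at 41.9 ± 4.08 signal units (SD) in CL1-0 and 35.2 ± 1.63 in CL1-5, and its log2 fold change of -0.21 did not pass (adjusted p = 0.10). With array weights CDH1 passed as lower in CL1-5. Of 7 tested keratins 2 were higher, also when adjusted over the list alone. These were the simple-epithelium pair KRT18 (6.31, SE 0.13) and KRT8 (3.32, SE 0.09). Each was tested through a probe set of the cross-hybridising kind, with 0 other tested probe sets, so signal from other transcripts may contribute. The keratin list passed camera at an adjusted p of 0.048 but not with an estimated correlation (adjusted p = 0.37) nor with the repeat number as a block (adjusted p = 0.072). Leaving out CL1-0 repeat 1 (adjusted p = 0.090), CL1-5 repeat 1 (0.065) or CL1-5 repeat 2 (0.068) also ended the keratin call. Its median was 0.24 within repeats 1 and 2 and 0.19 within repeat 3.

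Adhesion and matrix genes changed in both directions, more of them upward. Of 19 tested collagen and basement membrane genes 10 were higher and 3 lower, with COL5A2 at least 26.4-fold lower and LAMB3 (5.15, SE 0.12), COL6A1 (4.14, SE 0.21) and COL13A1 (at least 8.40-fold) higher. Of 17 integrin subunits 10 were higher and 3 lower, with increases of ITGA3 (3.55, SE 0.23), ITGA2 (2.77, SE 0.14) and ITGA4 (at least 3.90-fold) and a decrease of ITGAV (-2.31, SE 0.08). Both sets of counts were the same when adjusted over the list alone. The collagen list had a camera adjusted p of 0.029 and the integrin list one of 0.033. With an estimated correlation neither passed (adjusted p of 0.58 and 0.22). For the integrins that correlation was -0.046, under the preset 0.01, so correlation between genes does not account for their loss. Without CL1-5 repeat 1, 2 or 3 the collagen list had adjusted p of 0.062, 0.068 and 0.069, and the integrin list 0.15, 0.12 and 0.081. With the filter on 2 arrays, which keeps genes expressed in CL1-5 alone, the collagen list passed without any 1 array, and the integrin list failed only without CL1-5 repeat 1 (adjusted p = 0.0502). The collagen median was 0.36 within repeats 1 and 2 and 0.34 within repeat 3, and the integrin median 0.35 in both.

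Hypoxia-induced and glycolytic genes rose in 25 of 30 tested genes and fell in 2, or 26 and 2 when adjusted over the list alone, with a median of 1.16. The stress-responsive NDRG1 (3.84, SE 0.12), the phosphofructokinase regulator PFKFB4 (2.82, SE 0.09) and the vasodilator peptide gene ADM (2.81, SE 0.16) rose, while the glucose transporter SLC2A3 fell by 3.48 (SE 0.09). The camera adjusted p was 8.6e-10, and 0.027 with an estimated correlation. The median was 1.13 within repeats 1 and 2 and 1.24 within repeat 3. Angiogenesis factors were higher in 13 of 22 genes and lower in 4, also when adjusted over the list alone, with ANGPT2 at least 36.8-fold and NRP1 at least 11.5-fold higher and endothelin EDN1 lower by a log2 fold change of -2.84. That list passed camera (adjusted p = 0.033) but not with an estimated correlation (adjusted p = 0.27), nor without CL1-5 repeat 1 (0.081), 2 (0.075) or 3 (0.065), though with the filter on 2 arrays it passed without any 1 array. Its median was 0.52 within repeats 1 and 2 and 0.45 within repeat 3.

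The 1 list that passed camera with a lower level in CL1-5 was that of NRF2 targets and aldo-keto reductases, enzymes of detoxification and redox balance (adjusted p = 1.4e-04), and it did not hold with an estimated correlation (adjusted p = 0.12). Of 26 tested genes 19 fell and 3 rose, or 21 and 3 when adjusted over the list alone, with a median of -0.86. The export pump ABCC2 fell by 3.13 (SE 0.12) and glutathione reductase GSR by 2.66 (SE 0.23), while malic enzyme ME1 was at least 16.6-fold higher. AKR1C2 fell by 2.26 (SE 0.13), but its paralogs are near-identical, and with no filter another AKR1C2 probe set was taken, with a value of 0.24. The median was -0.88 within repeats 1 and 2 and -0.88 within repeat 3.

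**Figure D3:**
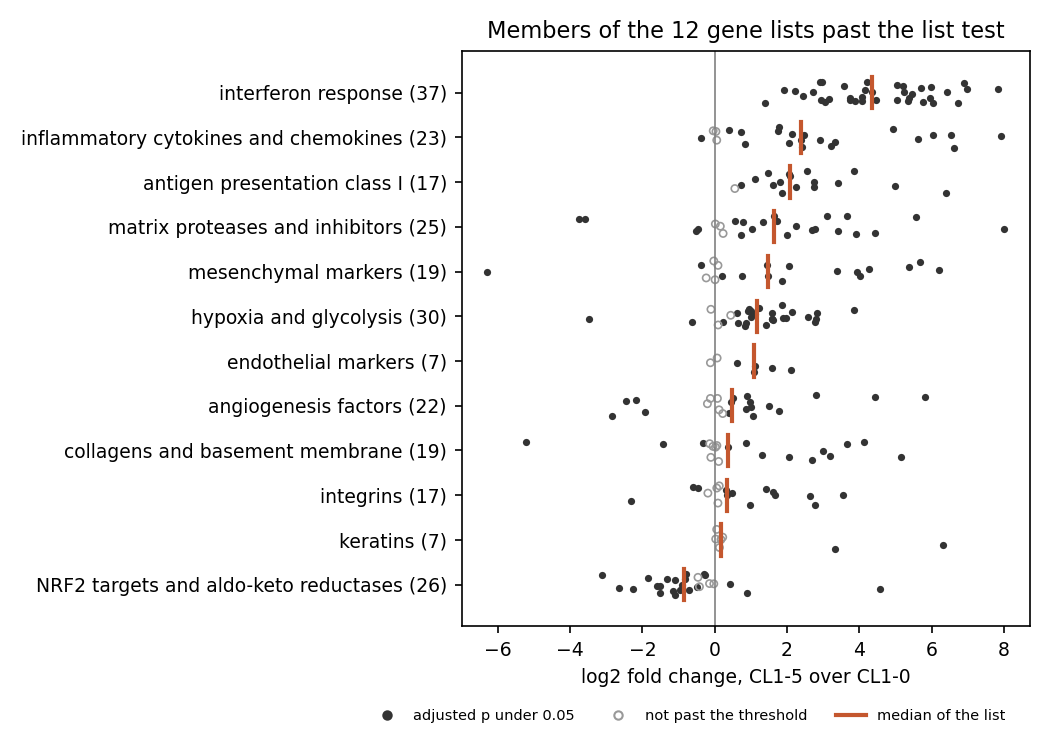
Log2 fold change of CL1-5 over CL1-0 for each tested member of the 12 gene lists that passed the list test, with the number of tested members in parentheses. Filled points passed the gene test at an adjusted p under 0.05, open points did not, and the vertical bar is the list's median. All 37 interferon response genes lie to the right of 0, and the median of the NRF2 targets, -0.86, lies to its left.

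Genes that earlier work on CL1 sublines had named for invasion were 4 higher and 2 lower of 7, also when adjusted over the list alone. As that list was drawn from these lines, it is not independent evidence of direction. It holds gene names without the direction each report gave, so the counts show neither agreement nor disagreement with those reports. SNAI2, CXCL8, CLDN1 and the receptor tyrosine kinase AXL (4.02, SE 0.14) rose. The semaphorin signalling protein CRMP1 (-3.19, SE 0.10) and the chaperone DNAJB4 (-2.40, SE 0.10) fell, and CDH1 did not pass. The list did not pass camera (adjusted p = 0.27).

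Signalling lists held large changes in both directions and did not pass. Of 27 TGF-beta genes 17 rose and 8 fell (camera adjusted p = 0.15), with the receptor TGFBR2 (4.69, SE 0.09) and TGM2 (5.27, SE 0.23) higher, INHBA at least 18.2-fold higher and ID2 lower (-5.38, SE 0.18). Of 25 Wnt pathway genes 10 rose and 6 fell (camera adjusted p = 0.16), with FZD6 at least 40.3-fold higher and the antagonists SFRP1 (5.36, SE 0.16) and DKK3 (4.15, SE 0.08) higher. Of 33 growth factor receptors and ligands 10 rose and 12 fell (camera adjusted p = 0.85), with FGF2 (-5.41, SE 0.21) and ERBB4 (at least 6.17-fold) lower and BTC at least 4.47-fold higher. Of 17 stemness and aldehyde dehydrogenase genes 3 rose, among them KLF4 (2.96, SE 0.09), and 6 fell (camera adjusted p = 0.41). Counts of these 4 lists were the same when adjusted over the list alone.

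Proliferation genes changed in both directions, and none of their lists passed. Of 35 G1/S genes 13 rose and 10 fell, 11 when adjusted over the list alone (camera adjusted p = 0.98), with CDC6 at -1.38 (SE 0.11) and CCNE2 at 1.11 (SE 0.18). Of 34 mitosis genes 6 rose and 14 fell, also when adjusted over the list alone (camera adjusted p = 0.54), with UBE2C at 1.34 (SE 0.13) and BIRC5 at -0.98 (SE 0.10). Of 23 cell cycle inhibitors and p53 targets 7 rose and 10 fell, also when adjusted over the list alone (camera adjusted p = 0.85). CDKN2A was at least 9.10-fold and its neighbour CDKN2B at least 2.38-fold lower, whereas CDKN1A (2.24, SE 0.09) and FAS (at least 4.33-fold) rose. This last list's direction was down by camera and by its median, and up by fry.

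Lineage, metabolic and housekeeping lists did not pass either. Of 14 lung lineage genes 2 rose, FOXA2 (at least 7.20-fold) and LPCAT1 (1.20, SE 0.11), and 2 fell, 1 when adjusted over the list alone (camera adjusted p = 0.88), with a median just under 0 and a mean just over it. NKX2-1, the lung lineage transcription factor, was dim in both lines and differed by -0.08 (adjusted p = 0.54). With repeats 1 and 2 alone, FOXA2 was tested through another probe set, at -0.14 (adjusted p = 0.41). Of 16 neuroendocrine and neuronal genes 6 rose and 7 fell (camera adjusted p = 0.98), with ENO2 at least 24.7-fold higher, a median of -0.23 (-0.13 with the dim genes at their bound) and a mean of 0.14. Of 18 xenobiotic genes 6 rose, among them MGST1 (at least 10.4-fold) and MGST2 (2.93, SE 0.11), and 6 fell (camera adjusted p = 0.74). Of 22 cholesterol synthesis genes 7 rose and 5 fell (camera adjusted p = 0.21), with MSMO1 at 1.64 (SE 0.08). Of 26 unfolded protein response genes 7 rose and 10 fell (camera adjusted p = 0.98), with DDIT4 at 2.10 (SE 0.08), DDIT3 at -1.49 (SE 0.15), a median of 0.06 and a mean of -0.01. Of 19 heat shock genes 4 rose and 9 fell, 10 when adjusted over the list alone (camera adjusted p = 0.32), with HSPB1 at -2.12 (SE 0.11). Of 30 respiratory chain genes 2 rose and 14 fell, 15 when adjusted over the list alone (camera adjusted p = 0.096), with NDUFA1 at -0.86 (SE 0.11), and the list passed without CL1-0 repeat 3 (adjusted p = 0.024, or 0.031 with the filter on 2 arrays) and with no filter (adjusted p = 0.047). Of 27 ribosomal protein genes 3 rose and 10 fell (camera adjusted p = 0.47), with RPS23 at -0.41 (SE 0.06), a call lost with the mean of the gene's probe sets. Of 9 cancer testis antigens 1 rose, MAGEB2 (at least 1.62-fold), and 5 fell (camera adjusted p = 0.27), with MAGEA4 at -0.97 (SE 0.13). Where no other count is given, those adjusted over the list alone were the same.

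Lists of markers of other cell types had low median signals, and 1 such list moved with the line. Endothelial markers had median signals of 25.4 in CL1-0 and 73.0 in CL1-5, and 5 of 7 were higher, also when adjusted over the list alone, among them TIE1 (at least 2.92-fold), CLDN5 (1.59, SE 0.17), PECAM1 (1.11, SE 0.11) and ESAM (1.07, SE 0.17). The endothelial list passed camera (adjusted p = 0.029) but not with an estimated correlation (adjusted p = 0.27), nor without CL1-5 repeat 1 (0.078), 2 (0.074) or 3 (0.065). With the filter on 2 arrays these 3 losses stayed, and one without CL1-0 repeat 2 (adjusted p = 0.10) joined them. Its median was 1.11 within repeats 1 and 2 and 1.00 within repeat 3. Of 8 leukocyte markers 2 rose, LCP1 (2.69, SE 0.16) and LAPTM5 (1.67, SE 0.15), and CORO1A fell by 1.12 (camera adjusted p = 0.47). Of 7 erythroid and liver markers 1 rose, SERPINA1 (2.27, SE 0.13), and 0 fell (camera adjusted p = 0.25). Counts of both lists were the same when adjusted over the list alone. The 4 tested fibroblast markers and the 4 tested squamous markers included 0 changed genes by limma, and both lists were too small for the list test. In all, 12 of 35 tested lists passed camera, 11 of them higher and 1 lower in CL1-5, and 6 held with an estimated correlation: mesenchymal markers, matrix proteases, interferon response, class I presentation, cytokines and hypoxia. The estimate lay under the preset 0.01 for the mesenchymal (-0.007), protease (-0.026), class I (0.006), cytokine (-0.005) and integrin (-0.046) lists. Their adjusted p rose all the same, so a larger p under that setting is not by itself a sign of correlated genes.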

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

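The tests of why repeat 3 stands apart were chosen after the result was seen.

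Control probe sets outside the gene comparison carried a signal on repeat 3. The 24 probe sets for Bacillus transcripts, which are added to RNA or cDNA as preparation controls, were brighter on repeat 3 than on repeats 1 and 2 by a median of 19.5-fold in CL1-0 and 42.7-fold in CL1-5. A shared preparation batch is consistent with these values and with the deviations of the repeat 3 arrays, which correlated between the lines at 0.649 over genes. Lower RNA integrity or shorter cDNA on repeat 3 may contribute, as the 3′ to 5′ ratio was highest on repeat 3 in 4 of 4 pairs of control gene and line. These explanations do not exclude each other, and no biological explanation was tested. Both lines have a repeat 3 array.

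Probe sets with no gene symbol here, which the gene comparison left out, also differed between the lines. Of 4259 tested, 486 were higher and 798 lower in CL1-5, with 166 at least 2-fold higher and 196 at least 2-fold lower.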

How the results depend on the processing

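The fits of repeats 1 and 2 alone, of the spike-in batch as a block and with the filter on 2 arrays were chosen after the data were seen. Over all alternatives, gene counts stayed within 1.5 times the main ones except over all probe sets, which counts probe sets and not genes (6686 higher, 8316 lower, 2560 and 2333 at least 2-fold). Leaving out 1 array gave 2692 to 3413 higher and 3486 to 4264 lower genes. The number of lists past the threshold was 7 at an adjusted p under 0.01, 6 with an estimated correlation, 30 by fry's directional and 35 by its mixed test, which compare no list with other genes, and 7 to 14 without 1 array. The 7 came without CL1-5 repeat 1 or 2. With the filter on 2 arrays the range was 9 to 13, with 9 and 10 without these arrays, so part of that loss came with the filter. With the replicate block 4145 genes were higher and 5149 lower, 7637 of the 7644 calls were kept, and 11 lists passed. The block ended the keratin call (adjusted p = 0.072) and no other call of a list or named gene. Repeats 1 and 2 alone gave 3276 higher and 4414 lower, or 3580 and 4645 with the filter on 2 arrays, and the spike-in batch as a block 4068 and 5027. Results that reversed did so mostly through another probe set. AKR1C2 stood at 0.24 with no filter, at -2.36 to 0.31 without 1 array (with the filter on 2 arrays 0.21 and 0.16 without CL1-0 repeat 2 and 3, and 0.31 and 0.30 without CL1-5 repeat 2 and 3) and at 0.22 with repeats 1 and 2 alone and the filter on 2 arrays. IL1A ranged from -0.54 to 6.06 without 1 array, or to 6.09 with the filter on 2 arrays, and stood at -0.26 with repeats 1 and 2 alone, and FOXA2 at -0.14. For IL1A, FOXA2 and TAOK1 the filter on 3 arrays had dropped the bright probe set, and with the filter on 2 arrays each call returned. For AKR1C2 that filter caused the reversals without 1 array. The cell cycle inhibitor list turned to higher under fry (adjusted p = 0.0096), and the cause was not tested. Named genes kept direction and side of the threshold in 3814 comparisons with an alternative, lost the call in 56, gained it in 2 and reversed in 11, and lists did so in 924, 41, 45 and 1. The 2 gains were CDH1 and COL1A2, both with array weights. Comparisons in which a gene or list was not tested, as where the filter dropped a gene, are not counted. Dim genes such as CDH1, CDH2 and NKX2-1 lie close to background, where small differences cannot be resolved.

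Of the 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05, 1 gave counts as large as the real ones, the real split itself. The real split gave 3448, 4196, 1262 and 1127 genes, and limma called 0 genes in any other, with 33 to 645 at an unadjusted p under 0.05, among them the 3 other splits that part all 3 pairs. Every other split mixes arrays of both lines in each group, so the line difference widens the spread within its groups. The 0 calls there follow from that mixing and say nothing about how many calls chance alone would give. For lists the real split gave 12 and the others 4 to 9. In every other split the lines are unequally shared between the groups, so part of the line difference remains. The 4 to 9 lists are therefore not a count that chance alone would give, and the 12 cannot be judged against them.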

Other observations

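The tests of a batch and of scaling on the interferon genes, and of a deletion over CDKN2A and CDKN2B, were chosen after the result was seen. The genes named in this part and in none of the lists were chosen after their values were seen.

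Genes for interferon sensing and signalling differed between the lines member by member. The lambda interferon receptor IFNLR1 (at least 8.05-fold), the RNA sensor TLR3 (at least 7.36-fold), the adaptor STING1 (3.07, SE 0.19), the feedback inhibitor SOCS1 (at least 15.4-fold) and the transcription factor IRF9 (2.90, SE 0.09) were higher in CL1-5. The kinases JAK1 (1.02, SE 0.08) and JAK2 (0.78, SE 0.11), the interferon gamma receptor subunits IFNGR1 (0.62, SE 0.10) and IFNGR2 (0.45, SE 0.09) and the feedback inhibitor SOCS3 (1.47, SE 0.15) were also higher. IL10RB, the partner subunit of IFNLR1, was lower (-0.33, SE 0.09). The receptor subunits IFNAR1 (-0.18, adjusted p = 0.20) and IFNAR2 (-0.43, adjusted p = 0.16), the kinase TYK2 (-0.05, adjusted p = 0.78), IRF3 (0.05, adjusted p = 0.70), MAVS (-0.13, adjusted p = 0.23) and CGAS (-0.10, adjusted p = 0.46) did not pass.

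For a set of 135 genes, the 1 probe set tested was near background on all arrays of one line and above the 75th percentile on all arrays of the other, though another probe set of the same gene can lie above background, as for CDKN2A, 85 bright in CL1-5 and 50 bright in CL1-0. Beyond the genes already named, those bright in CL1-5 included the granzyme inhibitor SERPINB9 (at least 68.9-fold), the DNA sensor IFI16 (at least 70.6-fold), the aminopeptidase ANPEP (at least 52.8-fold) and the death ligand TNFSF10 (at least 18.4-fold). Those bright in CL1-0 included the transcription factor MECOM (at least 52.2-fold), the inhibitor of differentiation ID4 (at least 28.4-fold), the peroxiredoxin PRDX2 (at least 24.7-fold) and cyclin CCND2 (at least 13.5-fold).

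For the interferon response list, each line had 1 repeat 3 array, so a batch shift common to both lines could not give the median of 4.35. The fit of repeats 1 and 2 alone therefore does not test such a shift. In it the median was 4.10 over the 32 members left by the filter on 3 arrays. With the filter on 2 arrays it was 4.42 over all 37, so the median did not rest on the repeat 3 arrays. Scaling between arrays was left untested, since the other scalings moved almost nothing (4.33 at the lowest). Leukocytes in the CL1-5 cultures are argued against by 1 of 6 leukocyte genes being at least 2-fold higher, with CORO1A lower (-1.12) and PTPRC and TYROBP under the filter. Interferon transcribed by the CL1-5 cells themselves is a candidate explanation. Of 18 ligand genes with a named probe set, 4 passed the filter, and the rest decide nothing. Of the 4, IFNL1 (1.34, SE 0.11) and IFNL2 (3.40, SE 0.10) were higher. IFNB1 (0.33, adjusted p = 0.051) and IFNA17 (0.08, adjusted p = 0.56) did not pass. Whether the higher ligand genes are a source or a result of the response was not tested. IFNL2 shares sequence with a near-identical paralog, protein was not measured, and other sources of interferon stay open.

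For the 135 genes, a deletion reaching the nearest bright gene on both sides is argued against. Of the 134 genes with such a neighbour on either side, 0% had both near background as well. Genes dim in both lines were passed over when neighbours were chosen. Loss of a single gene, or a smaller deletion with dim neighbours such as one around CDKN2A, was therefore not addressed by that test. For 76 of the 81 genes with another tested probe set, 93.8%, such a probe set changed the same way. In those 76 genes this argues against a fault of the chosen probe set alone. Probe sets near background in both lines failed the filter and were not counted, which raises that share. The share therefore does not show how many of the 135 genes rest on faulty probe sets. Genes with no other tested probe set were not addressed. A difference in regulation between the lines stays open as a hypothesis.

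Fold changes were also weakly alike along the chromosomes. A gene's log2 fold change correlated at 0.135 with the mean over genes 11 to 30 places away in the order of assembly GRCh38.p14, above the highest of 1000 shuffles (0.04), with a permutation p of 0.001, the smallest they can give. Of 1262 overlapping windows of 100 genes, 128 had a median outside those of 200 shuffles. Neighbouring windows share most of their genes, so the 128 are not separate regions. Regional differences in copy number may account for this, and regulation over large domains could give the same value.

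The tested probe sets of CDKN2A and CDKN2B lay near background in CL1-5, and a deletion that spans both genes in CL1-5 was tested through all their probe sets. Against it, 1 probe set, for CDKN2A, lay above the array median on all 3 CL1-5 arrays, at 45.9 signal units, after 1025 in CL1-0. That probe set is of the cross-hybridising kind, so that residual signal from other transcripts might account for it. The other 4 of the 5 probe sets lay above the 40th percentile on 0 CL1-5 arrays, as did 5 of the 6 probe sets of MTAP, a further neighbour, which goes with a deletion. Among them, 1 CDKN2A probe set (17.9 in CL1-0, 15.9 in CL1-5) and 1 MTAP probe set (10.0 and 9.18) were dim in CL1-0 too and cannot show a loss. A CDKN2B probe set (28.0 and 12.4) failed the filter and was not tested. The remaining MTAP probe set lay above that percentile on 3 CL1-5 arrays and did not differ by limma (-0.12, adjusted p = 0.46). It was dim in both lines (28.0 and 25.1), above the array median on 0 CL1-5 arrays, so it says little about a loss. The test is therefore weak, and a deletion stays open.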
